A study of Mus musculus with 8 samples.

How the data were processed

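DNA methylation was measured by RRBS in kidney cortex and outer medulla of male C57BL/6J mice, in 8 libraries of 6 groups, with 2 libraries each for UUO and for UUO with 5AZA and 1 library for each of the other 4 groups. Per the labels' protocols, DNA was cut with MspI, end-repaired with a nucleotide mix that held methylated dCTP, ligated to methylated adapters, size-selected, converted with bisulfite and amplified by PCR. The submitters' processing notes name Bowtie as the aligner and mm9 as the genome build, while the version of Bowtie, the methylation caller and any filters are not given in the sources used here. The deposited tables hold, for each CpG dinucleotide, a count of the reads covering it and a count of the methylated reads among them, made by the authors for each library and not normalized. They also hold the methylation level as a fraction that the authors rounded to 3 decimals, which equalled the ratio of both counts at that precision. Library groups were taken from the sample titles. The labels do not say that the libraries of a group came from separate animals, so p-values and SDs measure only the spread between these libraries, and its source, animals or technique, is unknown.

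The tables were joined on position with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Chromosomes 1 to 19, X and Y were kept, while random contigs were left out and mitochondrial positions were used only for the closing observations. A position needed at least 10 reads in every library, and a window of 1000 bp, counted from the first base of each chromosome, at least 3 such positions. Methylated and total reads were summed per library and window. The median number of reads per window and library was 264. Reads that cover several CpG positions are counted at each of them, and PCR copies are not told apart, so intervals cover counting error only and exact tests on summed reads give p-values that are too small. The UUO pair and the 5AZA pair differed by more than binomial sampling, with a mean chi-square per position of 1.23 and 1.18, so each library was counted as a sample of its own.

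For UUO against its sham and for 5AZA in UUO, a quasi-binomial logistic model with 1 mean per group was fitted over all 8 libraries. The Pearson dispersion was moderated with squeezeVar of limma 3.58.1 in R 4.3.3, and tested with a two-sided F test and Benjamini-Hochberg adjustment over 93730 windows. The spread came from the 2 pairs, with 2 residual degrees of freedom, a prior dispersion of 1.37 and 8.69 prior degrees of freedom, and single libraries were assumed to vary like the pairs. The moderated dispersion was not allowed below 1, a choice added after the design was fixed. A window was called at an adjusted p below 0.05 and a difference of at least 10 percentage points between group means. Ischemia libraries were compared with their sham by two-sided Fisher's exact test per window at an adjusted p below 0.01 and at least 25 points, and pairs of like libraries were counted in the same way. Confidence intervals of single libraries are exact binomial at 95%. Mean levels weight CpG positions or windows equally. Windows were classed by a sham library outside the difference, or by the mean of both ischemia libraries, at 10, 30, 70 and 90%. Simulated values for correlations are means of 20 sets of beta-binomial reads with the observed depth and dispersion and no group effect.

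Fragment edges were located from read depth alone. A position was counted as an edge when the depths of the 8 libraries changed by more than 10%, summed over libraries, to a neighbouring CpG within 250 bp that held at least 40 reads in total, or when it had no such neighbour. Of the positions kept, 58.0% were edges by this rule, and leaving them out left 33656 windows.

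The groups, tests, thresholds, window size, naming rule and most alternatives were set before the data were examined, while the fragment-edge setting, the trended dispersion, the mean reads per position, the level classes, the contrast of both injury models and the leave-one-out values of mean levels and correlations were added later. Named windows are the 10 largest rises and the 10 largest falls among called windows that moved in the same direction in every pair of libraries, and for ischemia the 5 largest rises and falls among counted windows with the same direction at both times. Fewer are described where the list was shorter or where the rest is given as a range. Alternatives were other read minimums, an upper limit on depth, windows of 300 bp, autosomes only, other minimum differences, limma on log2 ratios with a pseudocount of 1, edgeR 4.0.16 on methylated and unmethylated counts, other sets of libraries, a replicate block and reads thinned to equal depth. The annotation at hand used another genome build than mm9, so windows are named by coordinates alone. Gene names, promoter windows, the planned gene lists and the loci in the series title were not analysed here.

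The quasi-binomial test was tested on simulated data with the observed depths, 93730 windows and 200 changed windows for each size of change. All planted changes were rises in windows of low to intermediate level. The rates thus do not cover falls or highly methylated windows, while 413 of the 417 windows called for 5AZA were falls. For 5AZA in UUO it recovered 13.0% of changes of 10 points, 61.0% of 20 points and 91.5% of 30 points, with 4, 10 and 13 false calls, and for UUO against its sham there were 1, 8 and 10 false calls at the same sizes. Fisher's exact test was checked against scipy 1.17.1 on 300 tables. In simulated ischemia data, with rises planted in windows of low to intermediate level, it recovered 92.0% of rises of 30 points with 0 false calls. Figures were drawn with matplotlib 3.10.9.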

Results

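DNA methylation at CpG dinucleotides was measured by reduced representation bisulfite sequencing (RRBS), in which the enzyme MspI cuts genomic DNA at CCGG sites and short fragments are converted with bisulfite and sequenced, so that unmethylated cytosines read as thymines. The DNA came from the cortex and outer medulla of kidneys of male C57BL/6J mice. The 8 libraries fell into 6 groups. Unilateral ureteral obstruction (UUO), a surgical model of kidney fibrosis, was sampled at 7 days with 2 libraries, and 2 more came from obstructed mice given 5AZA at 1 mg per kg per day. Bilateral ischemia of 25 minutes was sampled after 1 week and after 1 month of reperfusion, with 1 library each. Each surgical model had its own sham-operated control, also with 1 library, so these 4 groups had no replicate check. The libraries held between 57853745 and 86411736 reads over CpG positions, with a median of 33 to 48 reads per covered position. At least 10 reads in every library were present at 976938 positions, which formed 93730 windows of 1000 bp.

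The first question was whether obstruction moved methylation of the measured fraction. Averaged over the shared positions, the level was 46.11% ± 0.029 (SD, n = 2) after UUO and 45.25% in the UUO sham, a difference of 0.86 percentage points. It was above 0 on 19 of 19 autosomes, between 0.63 and 1.04 points over the windows of each. Autosomes of the same libraries are not replicates. The single library of ischemia at 1 week was likewise below its sham on all 19, with differences of -0.74 to -0.45 points. The 2 shams, from different surgical series, differed by 0.95 points, so the UUO difference was not larger than the difference between sham libraries. The sham difference also holds any difference between the series, so it does not measure the spread within a series. With reads pooled over positions, which gives deep positions more weight, the difference was -1.82 points, and with each library averaged over its own positions it was -0.61 points. With fragment-edge positions left out the levels were far lower, 22.64% after UUO and 21.87% in the UUO sham, a difference of 0.77 points.

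The higher level after UUO was most marked in windows of intermediate methylation and, inside fragments, in those at 10 to 30%. Windows were classed by the ischemia sham, a library outside the comparison, and CpG positions at fragment edges were left out, because those positions read as methylated in unmethylated windows too. In the 2967 windows at 30 to 70% in that sham, the mean level was 54.03% in the UUO sham and 58.57% ± 0.09 (SD, n = 2) after UUO, 4.53 points higher. In the 1749 windows at 10 to 30%, it was 20.88% in the UUO sham and 25.25% ± 0.01 (SD, n = 2) after UUO. In the 20031 windows below 10%, it was 2.42% in the UUO sham and 2.89% ± 0.04 (SD, n = 2) after UUO, 0.47 points higher. In the 4036 windows at 70 to 90%, the UUO sham was at 83.5% and UUO at 84.51% ± 0.04 (SD, n = 2), 1.0 point higher. In the 4873 windows at 90% or more, the UUO sham was at 93.42% and UUO at 93.46% ± 0.13 (SD, n = 2), a difference within the spread of the UUO pair. Where windows were classed by the mean of both ischemia libraries instead, the difference in the 30 to 70% class was 4.65 points, and the 2 shams differed there by 2.55 points. Below 10%, classed likewise, UUO was 0.42 points higher, less than the 0.91 points between the shams. In the 30 to 70% class with edge positions kept, UUO was 2.71 points higher and the shams differed by 2.25 points. With the edge positions kept, the 30 to 70% class, then 15840 windows, was 2.92 points higher after UUO. The 70 to 90% class, then 22571 windows, was 1.18 points higher and the 10 to 30% class, then 20156 windows, 0.2 points. The class below 10% then held 1479 windows instead of 20031, so classes with and without edge positions held different windows. These class means, set against 1 sham library, were not tested.

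**Figure D1:**
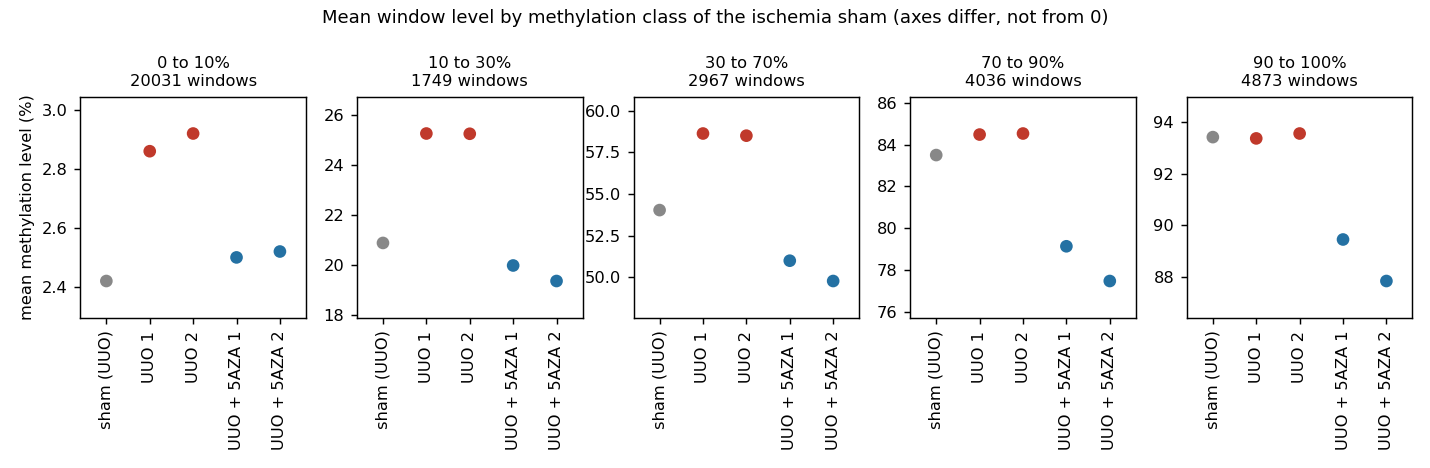
Mean methylation level (%, vertical axes, which differ between panels and do not start at 0) of 1 point per library in the obstruction series, for windows classed by their level in the ischemia sham with fragment-edge positions left out. In the 30 to 70% class the UUO sham was at 54.03%, the UUO mean at 58.57% and the mean with 5AZA at 50.38%; in the class at 90% or more only the 5AZA libraries stood apart, with a mean of 88.65%.

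Window by window, 17 of 93730 windows differed between UUO and its sham by at least 10 points at an adjusted p below 0.05 (moderated quasi-binomial model with limma), 15 higher and 2 lower after UUO. All 17 differed in the same direction in both UUO libraries, which the thresholds make likely, so this is no separate support. The 15 windows that rose lay on 10 autosomes and were CpG-rich, with a median of 28 measured CpG positions against 5 over all windows. The 2 falls were CpG-rich too, with a median of 49.5. Reads are summed over positions, so CpG-rich windows hold more reads and are more easily called. Their mean level was 32.7% in the sham and 47.4% after UUO. The largest rise was in a window on chromosome 11 from 97361001 to 97362000 (coordinates in build mm9), with 48 CpG positions. Its level was 36.21% in the sham (95% exact binomial interval 34.39 to 38.06) and 55.35% ± 0.61 (SD, n = 2) after UUO, a rise of 19.13 points (SE 1.19, adjusted p = 0.000947). A window on chromosome 12 from 70321001 to 70322000 rose by 18.74 points, from 56.56% to 75.30%. On chromosome 5, from 23988001 to 23989000, the level rose from 52.49% to 70.95%. On chromosome 10, from 79616001 to 79617000, it rose from 36.93% to 55.01%. A window on chromosome 7 from 52496001 to 52497000 rose from 33.71% to 50.40%. A window on chromosome 17 from 32533001 to 32534000 rose from 16.93% to 32.46%, and the other 4 named rises lay between 12.99 and 14.61 points. The 2 falls were on chromosome 16 from 36709001 to 36710000, where the level fell by 11.15 points from 94.26% to 83.11%, and on chromosome 15 from 100884001 to 100885000, where it fell by 10.41 points from 68.70% to 58.29%. Between 635 and 5920 reads lay behind each library's value in these 12 windows. At 20 reads per position 6 of the 12 no longer passed, among them those on chromosome 12 (16.90 points, adjusted p = 0.184) and chromosome 5 (16.77 points, adjusted p = 0.081) and the fall on chromosome 16 (-10.42 points, adjusted p = 0.0586). With both shams as 1 group the fall on chromosome 15 was -8.02 points, below the minimum of 10.

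The number of such windows differed widely between settings, with 2 residual degrees of freedom left by 8 libraries in 6 groups. It was 926 with only UUO and its sham in the model and with either 5AZA library left out, 295 without UUO 1, 1374 without UUO 2, 1 with edgeR and 0 with limma on log2 ratios, where 7421 windows had an unadjusted p below 0.05. With both shams as 1 group it was 293, with at least 20 reads per position 7, with windows of 300 bp 2 and with fragment-edge positions left out 121. In all of these counts other than 0 the windows that were higher after UUO outnumbered those that were lower. In simulated data for this comparison, rises were planted in 200 windows of low to intermediate level among 93730. The model recovered 3.0% of rises of 10 points, 54.5% of 20 points and 84.5% of 30 points. Smaller rises in such windows were thus mostly not detectable at this depth and number of libraries, and falls were not simulated.

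**Figure D2:**
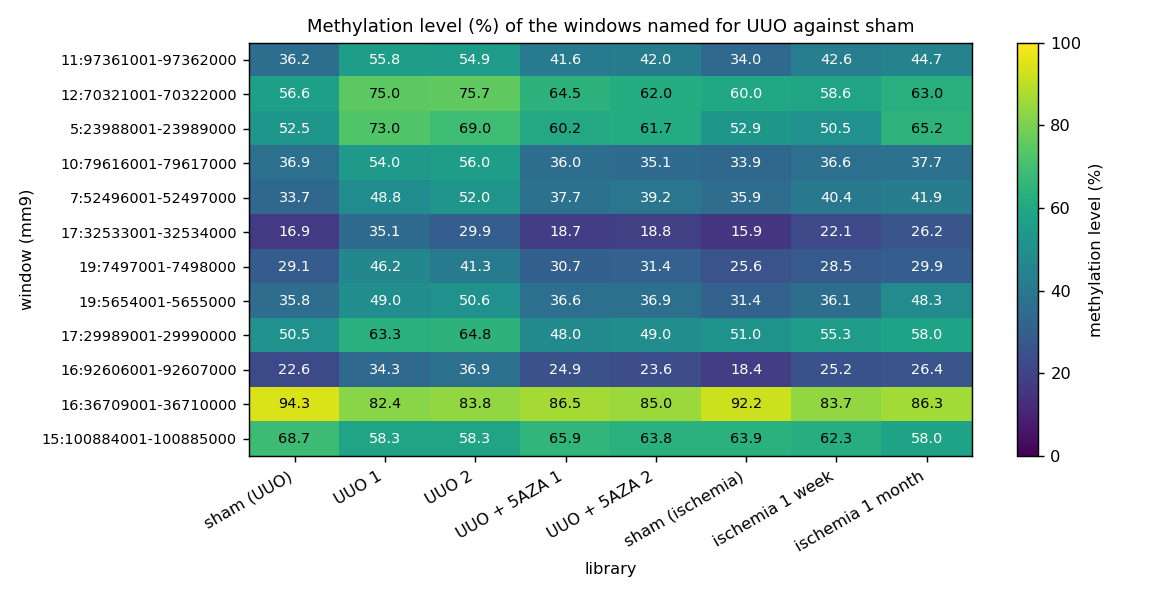
Methylation level (%, colour and number in each cell) in each of the 8 libraries (columns) for the 12 windows named for UUO against its sham (vertical axis, mm9 coordinates, rises first). In the first window the UUO libraries were at 55.78% and 54.91%, the UUO sham at 36.21%, and ischemia after 1 week and 1 month at 42.63% and 44.71% against 34.04% in its sham.

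The second comparison asked what 5AZA did to methylation in obstructed kidneys. Averaged over the shared positions, the level was 44.04% ± 0.305 (SD, n = 2) with 5AZA and 46.11% ± 0.029 (SD, n = 2) without, a difference of -2.07 points. Both 5AZA libraries lay below both UUO libraries, which gives p = 0.33 in a two-sided exact permutation test, the smallest p that 2 against 2 libraries allow. The mean over windows was lower on each of the 19 autosomes, with differences of -3.39 to -2.89 points, and -2.63 points on the X chromosome. These chromosomes are not replicates, as each library holds all of them. With reads pooled over positions the difference turned to 0.85 points, a setting in which the SD of the UUO pair was 1.024 points. With each library on its own positions it was -1.02 points. With fragment-edge positions left out it was -1.96 points, from 22.64% after UUO to 20.68% with 5AZA.

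With 5AZA, levels inside fragments were lower in all classes of windows at 10% or more, including those that UUO had left where they were in the sham. With fragment-edge positions left out, windows at 90% or more in the ischemia sham were at 88.65% ± 1.14 (SD, n = 2) with 5AZA, a difference of -4.82 points from UUO. The difference from UUO was -6.19 points in the 70 to 90% class, -8.19 points in the 30 to 70% class and -5.58 points in the 10 to 30% class. Set against the UUO sham, the 5AZA mean in these 4 classes changed by -5.11%, -6.21%, -6.76% and -5.81% of the sham's level, in order from the highest class. As a share of the UUO level the change was less even, at -5.15%, -7.33%, -13.98% and -22.08% in the same order, and -13.08% below 10%. In windows below 10% it was 2.51% ± 0.01 (SD, n = 2), against 2.89% after UUO and 2.42% in the sham. With the edge positions kept, the differences from UUO were -3.56, -4.64 and -4.46 points in the classes from 90% down to 30%. The 10 to 30% class changed by -0.14 points, within the SD of 0.37 points of the 5AZA pair. That class then held 20156 windows instead of 1749, so its values with and without edge positions are not of the same windows. By CpG density, over all positions, windows with 3 to 5 measured CpG positions changed by -4.02 points with 5AZA and windows with 20 or more by -0.04 points, within the SD of 0.29 points of the 5AZA pair. Inside fragments these differences were -4.69 and -0.19 points, the latter beyond the SDs of 0.02 points with 5AZA and 0.06 points after UUO, and came to -8.39% and -6.63% of the UUO level. Set against the UUO sham, the 5AZA mean in these density classes changed by -5.75% and 2.64% of the sham's level.

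In the same model, 417 windows changed between UUO with and without 5AZA, 413 of them lower with 5AZA, and all 417 moved in the same direction in each of the 4 pairs of libraries. A call already needs at least 10 points between group means, large against the spread of these libraries, so this agreement is no separate support. The 413 falls lay on all 19 autosomes, with none of the 1765 X-linked windows among them. Of the 413, 198 were at 30 to 70% and 204 at 70% or more in the UUO sham. Their mean level was 68.3% in the UUO sham, 77.0% after UUO and 62.1% with 5AZA, and in 321 of them, or 77.7%, both 5AZA libraries lay below the UUO sham, against 55.5% of all windows. The windows were picked for a high UUO level and a low 5AZA level alike, so selection raises the former mean and lowers the latter, and raises the share below the sham. The largest differences were -30.85 points (SE 4.56, adjusted p = 0.0365) on chromosome 12 from 13191001 to 13192000 and -30.69 points (SE 3.09, adjusted p = 0.00966) on chromosome 9 from 114625001 to 114626000. Without UUO 1 the chromosome 12 window no longer passed (-28.10 points, adjusted p = 0.0769), nor did it in edgeR (adjusted p = 0.0509). In the chromosome 9 window the level was 69.01% ± 2.12 (SD, n = 2) after UUO, 38.32% ± 2.09 (SD, n = 2) with 5AZA and 52.92% in the sham. Further falls were on chromosome 5 from 142032001 to 142033000, from 81.40% to 51.49%, on chromosome 4 from 83842001 to 83843000, from 84.35% to 56.25%, and on chromosome 10 from 79279001 to 79280000, from 88.88% to 61.10%. The other named falls lay between -28.04 and -24.90 points, and of these 1 no longer passed without UUO 1 and 1 without 5AZA library 2. These windows held few CpG positions, 3 to 8, with 50 to 407 reads per library. Of the 14 windows named for 5AZA, falls and rises together, 10 did not pass in edgeR.

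The 4 windows that rose with 5AZA were on chromosome 8 from 24319001 to 24320000, by 14.93 points, on chromosome 4 from 53727001 to 53728000, by 12.41 points, on chromosome 4 from 133428001 to 133429000, by 11.43 points, and on chromosome 12 from 81269001 to 81270000, by 11.10 points. In the first of these the UUO libraries were at 15.34% and 24.31%, the UUO sham at 31.45% and the 5AZA libraries at 33.99% and 35.53%. The chromosome 8 rise was 2.92 points at 20 reads per position and 3.51 points with an upper limit on depth, and the chromosome 12 rise 6.74 points at 20 reads, none of them past the threshold. Without UUO 1 the rise at 53727001 was 9.76 points and without UUO 2 that at 81269001 was 9.59 points, both below the minimum of 10. The count of 417 depended on the test, with 50 windows in edgeR and 0 in limma on log2 ratios, where 21039 had an unadjusted p below 0.05. Without UUO 1 it was 1622, without UUO 2 2855, without 5AZA library 1 3718 and without 5AZA library 2 1389, and with windows of 300 bp it was 11. In each of these counts other than 0, most of the windows were lower with 5AZA.

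The third comparison set ischemia against its own sham. The mean level was 43.77% after 1 week of reperfusion, 44.32% after 1 month and 44.31% in the sham, differences of -0.53 and 0.01 points. With reads pooled over positions the differences were 0.04 and -2.17 points, with each library on its own positions -0.03 and -0.13, and with fragment-edge positions left out -0.08 and 0.31. With fragment-edge positions left out and windows classed by the UUO sham, the 30 to 70% class was at 49.38% in the ischemia sham, 49.78% after 1 week and 52.27% after 1 month, and the 10 to 30% class at 17.03%, 17.42% and 19.14%. The 1-month library was thus 2.89 and 2.11 points above its sham in these classes, and the 1-week library 0.40 and 0.39 points. With the edge positions kept these differences were 0.87 and -0.32 points at 1 month and -0.49 and -0.37 points at 1 week. The classes then held different windows, 20036 instead of 1842 at 10 to 30% and 15499 instead of 2931 at 30 to 70%. The values with and without edge positions thus do not show whether the same windows kept their direction. Only the class mean at 30 to 70% at 1 month was above the sham in both settings.

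By Fisher's exact test on the reads of 2 libraries, which compares those libraries and not the conditions, 32 windows differed by at least 25 points at an adjusted p below 0.01 after 1 week, 13 higher and 19 lower, and 33 after 1 month, 16 higher and 17 lower. Counted in the same way, 26 windows differed between the UUO libraries, 49 between the 5AZA libraries and 66 between the shams. The shams came from different surgical series, so their count also holds any difference between the series. The ischemia counts were above that of the UUO pair and below those of the 5AZA pair and the shams, so they lay within the range of these pairs. With fragment-edge positions left out this held at 1 week, with 29 windows, but not at 1 month, with 44 against 27, 40 and 37 in the UUO pair, the 5AZA pair and the shams. With the spread of the UUO and 5AZA pairs in the quasi-binomial model with limma, 1 window passed after 1 week and 0 after 1 month, where 3805 and 4306 had an unadjusted p below 0.05. Both counts are a share below 0.05 of the 93730 windows, so low p-values were not in excess. UUO 1 and UUO 2 differed from their sham in 160 and 40 windows, and the 5AZA libraries from single UUO libraries in 84 to 287. The count of UUO 2 thus also lay within the range of the background pairs, while with edge positions left out it was 83, above them.

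**Figure D3:**
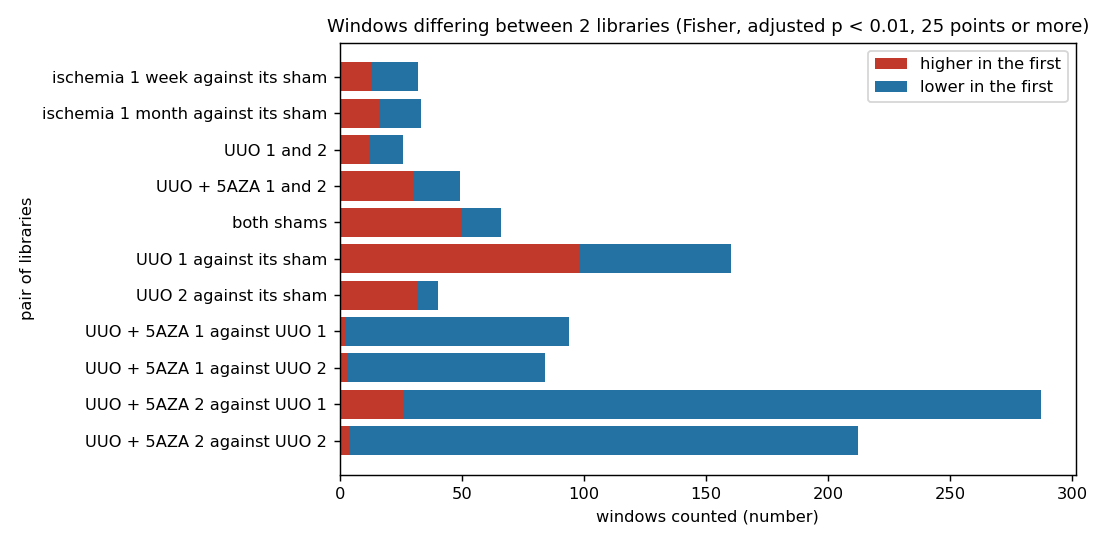
Number of 1000 bp windows (horizontal axis, from 0) that differed between 2 libraries by Fisher's exact test at an adjusted p below 0.01 and at least 25 points, 1 bar per pair of libraries, split into windows higher and lower in the library named first. The ischemia bars, at 32 and 33, lay between those of the UUO pair at 26 and the shams at 66; for the 5AZA libraries against UUO 2, 81 of 84 and 208 of 212 windows were lower.

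Of the windows counted at 1 week and 1 month, 9 were counted at both times, all in the same direction, with the sham library shared by both. A window on chromosome 15 from 79891001 to 79892000 was at 91.5% in the ischemia sham (95% exact binomial interval 88.0 to 94.3, 331 reads), 65.9% after 1 month, and it fell by 31.59 points after 1 week. The same window was at 91.2% in the UUO sham and at 64.2% and 63.8% in the UUO libraries. A window on chromosome 13 from 120276001 to 120277000, with 13 CpG positions, was at 58.3% in the ischemia sham, 26.9% after 1 week and 33.0% after 1 month, but the UUO sham was at 39.9% (95% exact binomial interval 37.0 to 42.9), nearer to the ischemia libraries than their own sham was. On chromosome 15 from 79255001 to 79256000 the level was 95.7% in the sham, 49.2% after 1 week and 68.0% after 1 month. Among the higher windows, one on chromosome 7 from 25919001 to 25920000 was at 24.5% in the sham, 52.8% after 1 week and 55.7% after 1 month, and at 55.7% and 63.7% in the UUO libraries against 38.0% in the UUO sham. On chromosome 5 from 123820001 to 123821000 the ischemia sham, at 34.4% with 61 reads, lay below the other sham, at 70.1%, so the difference of 45.57 points after 1 month rested on that sham library. Against the UUO sham, 7 of the 10 windows named at 1 week and 7 of the 10 named at 1 month no longer passed. With reads thinned to equal depth 6 and 5 no longer passed, and with mean reads per position 10 and 10.

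The injury models were then set side by side without any shared library. Of the 15 windows that rose after UUO, 15 were higher than the ischemia sham after 1 month of reperfusion and 13 after 1 week, with mean differences of 7.32 points (SD 3.90 over windows) and 3.28 points (SD 3.10 over windows). Among the 27552 windows in the same range of sham levels, 44.7% were higher at 1 month and 42.0% at 1 week. Matching here, and for the shares given below, was on the level alone, with edge positions kept, and not on CpG positions or reads. Classed by the UUO sham, 20036 windows lay at 10 to 30% with edge positions kept and 1842 without them. Many of the matched windows may thus read higher than their inner positions, so these shares are only a loose yardstick. Both windows that fell after UUO were also lower in both ischemia libraries. In the other direction, 18 windows were lower at both ischemia times and counted at 1 week, and 14 of them were lower in both UUO libraries than in the UUO sham, with a mean difference of -9.28 points (SD 8.97 over windows). Among all windows in their range of levels, 27.1% were lower in both UUO libraries. For the 11 windows that were higher and counted at 1 week, 5 were higher in both UUO libraries, against 50.7% of all windows in their range.

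Across all 93730 windows, which are not independent replicates, the UUO difference correlated weakly with that of ischemia at 1 month (Pearson r = 0.201, Spearman rho = 0.142, same sign in 53.0% of windows) and hardly with that at 1 week (r = 0.022, rho = 0.003, same sign in 48.0%), where r was 0.040 without UUO 1 and 0.003 without UUO 2. With fragment-edge positions left out the correlations at 1 month and 1 week were 0.300 (rho = 0.152) and 0.113 (rho = 0.063). In simulated data over all positions without any effect they were -0.002 and 0.000. The ischemia differences at 1 week and 1 month correlated at r = 0.562 when both used the ischemia sham, with a simulated value of 0.578 for unchanged libraries sharing a sham and a covariance of 9.266 against 8.647 in the simulation. With different shams the correlation was 0.009 or 0.034, depending on which time was set against which sham. A contrast of the UUO effect against the ischemia effect in limma on log2 ratios gave 0 windows at 1 week and 0 at 1 month, with 5854 and 5307 at an unadjusted p below 0.05, and the contrast was run in no other tool. Since limma on log2 ratios also called 0 windows for UUO against its sham and for 5AZA in UUO, this leaves open whether the effects differed.

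The last comparison asked whether 5AZA lowered the windows that had risen after UUO. The shared UUO libraries alone give a negative correlation between both differences, so each UUO library was used on only 1 side. UUO 1 minus sham correlated with 5AZA minus UUO 2 at r = -0.177 (rho = -0.144), and UUO 2 minus sham with 5AZA minus UUO 1 at r = -0.261 (rho = -0.212). In simulated data without any effect the values were 0.001 and 0.000. No loss with 5AZA was simulated, so they cannot tell a reversal from a loss that follows the level. Inside fragments, windows at 30 to 70% in the ischemia sham had both the largest rise after UUO, 4.53 points, and the largest change with 5AZA, -8.19 points. With shared UUO libraries the correlation was -0.517, against -0.406 in the simulation, and the covariance -9.135 against -4.243. Of the 98 windows higher in UUO 1 than in the sham by Fisher's exact test, 80 were lower with 5AZA than in UUO 2, a share of 81.6% against 78.1% of all windows. Their mean difference was -6.32 points (SD 7.02 over windows), against -3.95 points in windows of the same UUO 2 level. Of the 32 windows higher in UUO 2, 30 were lower with 5AZA than in UUO 1, a share of 93.8% against 75.8% of all windows, with a mean of -10.15 points (SD 7.47 over windows) against -3.86 points in level-matched windows. For the 62 windows lower in UUO 1 than in the sham, the mean was -3.71 points against -2.85 in level-matched windows, and for the 8 windows lower in UUO 2 it was -1.27 points (SD 11.32 over windows) against -3.63, with 37.5% of them lower with 5AZA. Of the 15 windows called higher after UUO, 10 were also called lower with 5AZA, where independent lists of these lengths would share 0.066, but both lists used the same UUO libraries.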

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

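The comparison below was chosen only after the mean levels had been seen. Over the shared CpG positions, both UUO libraries were above their sham, by 0.84 and 0.88 points, while the ischemia library at 1 week was 0.53 points below its own, a signed difference of -0.53. The effects of both injuries thus lay 1.4 points apart in opposite directions. The difference of mean levels was not tested. The directions depended on the setting: with reads pooled they were exchanged, with UUO at -1.82 points and ischemia at 0.04, and on each library's own positions both were below 0, at -0.61 and -0.03. Without edge positions they stayed opposite, at 0.77 and -0.08. The 1-month library differed from the same sham by 0.01 points.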

How the results depend on the processing

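The counts for UUO and for 5AZA kept their leading direction in every alternative with a count above 0, but not their size. The count for ischemia at 1 month did not keep its leading direction. The cause of these changes was not tested. Leaving out a library of a pair left 1 residual degree of freedom and raised the counts. The prior degrees of freedom were estimated anew in each refit of the quasi-binomial model. Fragment-edge settings, mean reads per position and the leave-one-out values of levels and correlations were chosen after seeing the data. For UUO against its sham (17), the count was 0 at 25 points, 293 with both shams, 926 with only the groups compared, 295 to 1374 with a replicate left out, 7 at 20 reads, 2 at 300 bp, 121 without edge positions, 0 in limma and 1 in edgeR. For 5AZA in UUO (417) it was 712 with no minimum difference, 9 at 25 points, 1389 to 3718 with a replicate left out, 644 at 5 reads, 263 at 20 reads, 11 at 300 bp, 0 in limma and 50 in edgeR. With the replicate number as a block it was 3582, but deviations of same-numbered libraries correlated at only 0.070, so the numbers are not taken to pair the samples. For ischemia at 1 week (32) the count was 17 thinned to equal depth, 260 at 10 points, 0 with mean reads per position, 18 at 20 reads and 1 with the pairs' spread. At 1 month (33) it was 435 at 10 points, 0 with mean reads per position, 74 with the other sham, 51 at 5 reads, 16 at 20 reads and 0 with the pairs' spread. For the UUO pair (26) it was 14 thinned, 387 at 10 points, 0 with mean reads per position, 40 at 5 reads and 4 at 20 reads. For the 5AZA pair (49) it was 475, 2, 81 and 20 in the same order without thinning, and for the shams (66) 598 at 10 points, 2 with mean reads per position, 36 at 20 reads and 37 without edge positions. With reads pooled, the mean level difference was 0.85 points for 5AZA, -1.82 for UUO, 0.04 for ischemia at 1 week and -2.17 at 1 month, against -2.07, 0.86, -0.53 and 0.01. On each library's own positions it was -1.02, -0.61 and -0.03 for the first 3, and without edge positions -0.08 at 1 week and 0.31 at 1 month. The correlation of UUO with ischemia at 1 month (0.201) was 0.181 at 5 reads, 0.237 at 20 reads, 0.250 in windows at 20 to 80%, 0.300 without edge positions and 0.178 to 0.185 with 1 UUO library, and at 1 week (0.022) it was 0.113 without edge positions, 0.040 without UUO 1 and 0.003 without UUO 2. The correlation of both UUO differences with 5AZA (mean -0.219) was -0.288 in windows at 20 to 80% and -0.294 without edge positions. Of 12 windows named for UUO none changed sign, 12 did not pass in limma, 11 not in edgeR and 6 not at 20 reads, and of 14 named for 5AZA 14, 10 and 2. The last count leaves out windows with too few positions at 20 reads to be tested, such as the largest fall, on chromosome 12. The window on chromosome 11 from 74655001, at 32.15 points after 1 month, was at -0.06 points against the other sham. Promoter windows of gene lists were not run. At 10 points the test recovered few simulated rises, so depth and replicate number limit what the counts can show. Falls were not simulated.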

Other observations

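All tests in this part were chosen after the results they bear on had been seen. Mitochondrial DNA, which was outside the window comparisons, took a smaller share of reads in the injured kidneys. In ppm of nuclear CpG reads, mitochondrial CpG reads came to 2126 in the UUO sham, 413 and 610 in the UUO libraries, and 491 and 1162 with 5AZA. The ischemia sham had 2111, ischemia at 1 week 793 and ischemia at 1 month 1521. As a control, reads on the Y chromosome came to 99.5 to 118.3 ppm in the same 8 libraries. Along the nuclear chromosomes, the X chromosome was 0.38 points higher after UUO than in the sham over 1765 windows, below the range of the autosomes.

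Selection of fragments by length was examined on 1 mitochondrial run of CpG positions of like depth, from 3333 to 3402. In the UUO libraries it lay 5.12 and 4.29 SDs below 6115 nuclear runs with a CpG span within 10 bp of its own. In the 5AZA libraries it lay 4.18 and 1.99 SDs below. The span from first to last CpG is not the fragment length, so the test cannot decide on selection by length. Depth is argued against as the cause of the lower mitochondrial share after UUO. The total of the sham lay between those of the UUO libraries, and its share was 3.48-fold that of the nearer one. A lower content of mitochondrial DNA in injured kidney may be the cause and stays open as a hypothesis. In ischemia at 1 month the share was 0.721 of the sham's, and the mitochondrial run lay only 1.01 SDs below the nuclear runs, with 1 sham library per series.

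In 16931 windows of at least 10 positions with a median position below 10%, 18.3% of single CpG positions had a mean level over 30%, and these had mean levels of 69.5 to 74.5% across libraries. Conversion that failed along whole fragments is argued against by 7008 windows with at least 30 positions, chosen without regard to level, where positions inside fragments averaged at most 3.2% in any library. Methylation of the kidney genome that does not follow fragment ends is argued against by the same 7008 windows. There, edge positions averaged 27.5 to 30.2% across libraries, against 1.9 to 3.2% inside fragments. Methylation confined to the sites at fragment ends stays open, since mitochondrial edge positions, at 66.7% or more in each library, were only 3. Of the high positions, 99.1% lay at steps of read depth, against 33.3% of the other positions. Methylated dCTP filled in at MspI ends during end repair may be the source, as the labels' protocol names that nucleotide, but conversion failing only at fragment ends was not tested.

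Levels were lower with 5AZA in all classes of methylated windows, inside fragments. A better bisulfite conversion of unmethylated cytosines in the 5AZA libraries is argued against by windows below 10%, where most cytosines are unmethylated. They lost 0.08 of the points that the least affected methylated class lost. At 2.89% after UUO, these windows could not have lost as many points as that class. The value does not bear on conversion of methylated cytosines, which was not tested. A loss limited to what obstruction had added is argued against by windows at 90% or more, which UUO had moved by 0.05 points and which changed by -4.82 points with 5AZA. A loss spread over methylated windows in general may underlie the pattern, and a difference between library batches could not be examined, since the labels give no batch.

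The mean level left inside fragments of unmethylated windows differed between the surgical series. It was 2.14 to 2.49% in the 5 libraries of the obstruction series, sham included, and 1.24 to 1.33% in the 3 libraries of the ischemia series. The 3 mitochondrial positions inside fragments read 1.14 to 1.47% and 0.36 to 0.42% in the same order of series.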
